A study of Mus musculus with 6 samples.

How the data were processed

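Bulk RNA-seq was made from pieces of mouse spinal cord spanning segments T8 to T12, collected 3 days after surgery from C57/BL6 animals. The sham group (3 libraries) had the cord exposed by laminectomy, the removal of the bony roof of a vertebra. The injured group (SCI, spinal cord injury, 3 libraries) had the exposed cord crushed briefly with a vascular clip as well. Per the labels' protocols, polyadenylated RNA was selected, the second cDNA strand was marked with dUTP so that reads keep their strand, and the adapters carried unique molecular identifiers. Each library was named here by its group and the replicate number in its title.

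The deposited values were FPKM (fragments per kilobase of gene model, scaled to the fragments of the library), given by the authors for each gene and library to 2 decimals, per the file headers. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, UMI-tools, StringTie 1.3.4d, DESeq2 and edgeR, without the role or order of each. The strand setting used for quantification, and how identical molecular identifiers were merged, are not given in the sources used here. The notes name the genome build mm9. The gene coordinates in the files are however those of GRCm38 (mm10): of the 36502 gene identifiers shared with GENCODE M21, 33485 (91.7%) had the same chromosome, start and end, so coordinates are given on GRCm38 as the files list them.

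FPKM values hold no read counts, and the depth behind them is unknown. The values of low genes were searched for steps that would show whole reads. Between sham replicate 1 and each other library, the fullest bin of log2 ratios (width 0.05) held from 3.37% to 4.39% of 1247 to 1489 short low genes, so no step common to all genes was found and no depth was recovered. FPKM summed to between 716215 and 734791 per library. Because FPKM are shares of a library, a gene that takes a large share lowers the values of all others. The 37 mitochondrially encoded genes took 19.2% to 24.1% of the FPKM, and the 4 haemoglobin genes took 0.11% to 0.13% in the sham libraries and 0.66%, 6.16% and 0.21% in SCI replicates 1, 2 and 3.

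The design, the gene lists, the rule for named genes and the alternatives given here, apart from those said to be added, were fixed before the data were examined. The design assumed counts and named a replacement for FPKM. Since the files held FPKM, the planned quasi-likelihood test of counts in edgeR was not run and the replacement was used: limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested, which kept 17435 of 36629. All 6 libraries entered a model with group as its term. P-values were adjusted with the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as past the threshold. Fold changes are SCI minus sham on the log2(FPKM + 1) scale, which understates the change of low genes, and SE is limma's moderated standard error.

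The 38 gene lists hold 420 genes of cell types, pathways and other tissues that a piece of cord could carry, and 418 of them had a value. The 37 lists with at least 3 tested members were tested with camera, limma's competitive set test, at a preset inter-gene correlation of 0.01 (two-sided) and adjusted over the lists. The same lists were tested with a correlation estimated per list. Camera then takes its degrees of freedom from the libraries in place of the genes, which by itself gives larger p-values. The lists were also tested with fry, limma's self-contained set test. It asks whether the genes of a list move on balance one way and does not compare them with other genes. Counts of changed members come from the adjustment over all genes tested. They were also adjusted over the list alone, and that second count is given where it differed, which was so in 9 lists.

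The genes named in the text were chosen by a rule. It took Gas6, Axl, Mertk, Tyro3, Pros1, Gfap, Aif1, Il1a, Tnf and C1qa in every case. It added the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold, with a mean of at least 5 FPKM and groups that did not overlap. From each list it took the 2 past the threshold with the largest change and the 2 most abundant. The rule gave 136 genes, and 122 were past the threshold. Values of some of these genes are not reported here. A further 59 tested genes were chosen after their values were seen, mostly members that went against their list or did not pass. Of the 136, 26 overlap another gene with a mean of at least 1 FPKM, so that reads could be shared between them. The values of near-identical copies, among them Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, H2-D1, Ly6c1 and the nuclear copies of mitochondrial genes, are uncertain for the same reason.

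The test was checked on simulated data with the 17435 tested genes, 3 libraries against 3 and 50 changed genes per size. At a simulated log2 change of 0.5, 24% of the changed genes were recovered. At 1, 2 and 4 the share was 76%, 94% and 96%. Of 165 calls, which include members of a planted list of changed genes besides these, 6 were false (3.6%). The planted list was recovered, and 0 of 50 random lists were called by camera. The simulated genes varied independently, whereas list members in the data moved together, with an estimated correlation of 0.86 for pan-neuronal genes. The 0 of 50 therefore says nothing about false calls in correlated lists. Far fewer genes changed in the simulation than were called in the data, so the recovered shares hold for that setting only.

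The labels give no statement that each library came from a separate animal, although the design text counts 3 per group. P-values therefore measure the spread between these samples, part of which may be technical. The labels give no sequencing batch or date. Sham and SCI libraries carry the same replicate numbers, and a fit with that number as a block was among the alternatives.

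The alternatives were quantile normalization, no filter on low values, a filter at 5 FPKM, a pseudocount of 0.1, limma's treat against a log2 change of 1, the replicate block, and leaving out each library in turn. For the lists they were camera with an estimated correlation and fry. Alternatives that need counts (DESeq2's Wald test, DESeq2 size factors in an edgeR fit, upper quartile factors, and library totals without TMM factors) were not run. A scaling by median ratios and a fit without mitochondrial and haemoglobin genes were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.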

Results

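The transcriptome of the injured mouse spinal cord was measured by RNA-seq 3 days after a clip crush and set against sham-operated cord, with 3 libraries per group. The stated purpose was to compare injured with uninjured cord at the centre of the lesion, and the series title places the comparison in the context of Gas6/Axl signalling and of microglia and astrocytes. Values are the authors' FPKM, given as mean ± SD with n = 3 per group. Between 16774 and 17202 genes reached 1 FPKM in a library. On log2(FPKM + 1), libraries correlated with Pearson r of 0.987 within the sham group and 0.971 to 0.985 within the SCI group, against 0.839 to 0.907 between groups. The leading principal component held 84.1% of the variance and separated the groups.

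The injured cord differed from the sham cord in 10024 of 17435 genes tested, and the largest rise was that of Arg1. Arg1, the arginase of alternatively activated macrophages, went from 0.677 ± 0.221 to 364 ± 243 FPKM (n = 3 per group). Timp1, an inhibitor of matrix metalloproteinases, went from 2.38 ± 0.356 to 452 ± 244, and Lgals3, the galectin of phagocytes, from 3.00 ± 0.355 to 262 ± 45.9. Among the largest falls, Chodl, a marker of fast motor neurons, went from 22.1 ± 7.14 to 1.09 ± 0.591 FPKM. Slc5a7, the choline transporter of cholinergic terminals, went from 42.4 ± 5.26 to 6.03 ± 1.94. On the log2 scale the 10 largest rises included Arg1 (7.53), Timp1 (6.93), Lgals3 (6.03), Tgm1 (6.0), Sprr1a (5.84), Thbs1 (5.83), Hmox1 (5.74), Pf4 (5.69) and Ccl2 (5.15). The 10 largest falls included Myoc (−3.77), Hoxd10 (−3.68), Chodl (−3.46), Kcnj14 (−2.84), Fam178b (−2.75), Slc5a7 (−2.65), Dao (−2.62), Uts2b (−2.60) and Ddn (−2.59). Among these genes the highest limma adjusted p was 0.0054, that of Hoxd10, and none lost its call when any 1 library was left out. In all, 4653 genes were higher and 5371 lower, and 7411 did not pass. With a log2 change of at least 1 as well, 1915 were higher and 905 lower. The libraries of the groups did not overlap for 11780 genes (67.6%), where chance gives 10% with 3 against 3.

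Members of the Gas6 and TAM receptor pathway moved apart. Axl, a receptor tyrosine kinase of the TAM family that binds Gas6, rose 2.70-fold, from 31.1 ± 1.62 to 83.9 ± 10.9 FPKM. Mertk, the TAM receptor of phagocytes that clear dying cells, rose 2.69-fold, from 8.74 ± 1.40 to 23.5 ± 3.34. Pros1 (protein S), a ligand of Tyro3 and Mertk, rose 5.04-fold, from 15.5 ± 2.82 to 78.4 ± 6.57. Gas6 itself fell 1.49-fold, from 149 ± 4.85 FPKM to 97.3, 88.1 and 115 in the SCI libraries (SD 13.5), and Tyro3, the TAM receptor abundant in neurons, fell 1.55-fold, from 29.8 ± 1.69 to 19.2 ± 5.01. Each of these changes separated all 3 SCI from all 3 sham libraries.

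In limma the log2 changes were 1.40 for Axl (SE 0.11, adjusted p = 7.8e-05), 1.33 for Mertk (SE 0.14, adjusted p = 3.1e-04) and 2.27 for Pros1 (SE 0.14, adjusted p = 3.0e-05). They were −0.57 for Gas6 (SE 0.10, adjusted p = 0.0030) and −0.64 for Tyro3 (SE 0.18, adjusted p = 0.018). Adjusted over the list alone, the p-values were 9.5e-04 for Gas6 and 0.0084 for Tyro3. The fall of Tyro3 no longer passed without sham replicate 2 (log2 change −0.62, adjusted p = 0.056) or without sham replicate 3 (−0.61, adjusted p = 0.057), and its size was −0.43 without SCI replicate 2. Socs3, an inhibitor of cytokine signalling that was counted in the same list, rose from 2.25 ± 0.180 to 62.4 ± 16.2 FPKM (log2 change 4.25). Socs1 was too low to test, at 0.14 to 0.62 FPKM in sham and 0.55 to 1.01 in SCI libraries. The list as a whole had 4 members higher and 2 lower of 6 tested and did not pass camera (adjusted p = 0.059). It did pass (adjusted p = 0.037, 0.047 and 0.047) without sham replicate 2, sham replicate 3 or SCI replicate 1, under quantile normalization (adjusted p = 0.048) and with no filter on low values (adjusted p = 0.013).

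On GRCm38, Gas6 lies on chromosome 8 from 13465374 to 13494490 on the minus strand, where it overlaps Tmem255b, and Axl on chromosome 7 from 25757273 to 25788705 on the minus strand. Mertk and Tyro3 lie on the plus strand of chromosome 2, from 128698956 to 128802894 and from 119797733 to 119818104, and Mertk overlaps Gm23172. Pros1 lies on the plus strand of chromosome 16, from 62854307 to 62929346. Their identifiers in the files are ENSMUSG00000031451, ENSMUSG00000002602, ENSMUSG00000014361, ENSMUSG00000027298 and ENSMUSG00000022912, in that order. The values are totals over each gene.

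**Figure D1:**
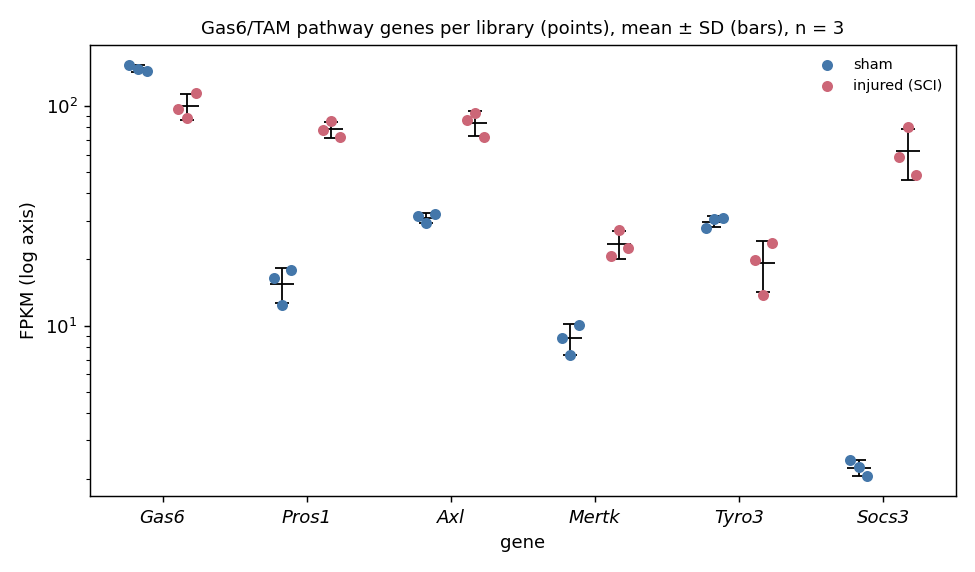
FPKM of Gas6, Pros1, Axl, Mertk, Tyro3 and Socs3 on a log axis, with 1 point per library, sham in blue and SCI in red, and black bars for the mean ± SD of 3 libraries. Gas6 sits at 88.1 to 115 FPKM in SCI libraries, below the sham libraries at 144 to 154, while Axl sits at 72.0 to 93.3 in SCI libraries, above the sham libraries at 29.2 to 32.3.

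Genes of microglia and macrophages were higher in the injured cord. Aif1, which encodes the microglial marker Iba1, rose 5.86-fold, from 4.86 ± 0.710 to 28.5 ± 3.92 FPKM. Homeostatic microglial genes had 11 of 12 members higher, among them Fcrls (log2 change 3.44) and Olfml3 (2.84), while Siglech had a log2 change of −0.25 that did not pass. Genes of activated, disease-associated microglia had 17 of 18 members higher, among them Gpnmb (4.72) and Spp1, or osteopontin, which went from 236 ± 19.8 to 3944 ± 1367 FPKM. Ctsd, the protease cathepsin D, went from 440 ± 14.4 to 2570 ± 335. Apoe, at 1230 ± 128 in sham and 1453 ± 203 in SCI libraries, did not pass (log2 change 0.24), and its value was −0.025 under quantile normalization. Genes of monocyte-derived macrophages had 13 of 13 members higher, with Clec4d at 4.88 and Lyz2, the lysozyme of myeloid cells, at 3.46, and 11 of the 13 were highest in SCI replicate 2 among the injured libraries. In camera the adjusted p was 8.1e-06 for the homeostatic, 3.0e-10 for the activated and 1.1e-07 for the monocyte list. These became adjusted p = 0.23, 0.20 and 0.23 with an estimated correlation.

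Reactive astrocyte genes rose, and genes of astrocyte homeostasis went both ways. Gfap, the intermediate filament of reactive astrocytes, rose 4.34-fold, from 641 ± 116 to 2781 ± 63.0 FPKM. Pan-reactive genes had 12 of 13 members higher, led by Timp1 and by Serpina3n, a protease inhibitor, which went from 56.4 ± 1.60 to 1167 ± 246. Steap4 had a log2 change of 0.50 that did not pass, and was at 0.24 without SCI replicate 3 and 0.71 without SCI replicate 1. The list of A2-type reactive genes, defined elsewhere after ischaemia, had 12 of 12 members higher, among them Tgm1, Emp1 (3.92), Tm4sf1 (3.49) and S100a10 (2.35). The list of A1-type genes, defined elsewhere after endotoxin, had 8 of 11 members higher, among them Srgn (3.27), Ggta1 (2.22) and H2-D1 (1.21). Adjusted over the list alone, 9 were higher. In that list Amigo2 was lower (−0.55), and Serping1 (0.74) and Fbln5 (−0.03, and 0.050 under median-ratio scaling) did not pass. The call on Amigo2 ended without sham replicate 1 (−0.40), sham replicate 3 (−0.53), SCI replicate 1 (−0.49) or SCI replicate 2 (−0.43), and Serping1 passed without sham replicate 2 (0.36) or sham replicate 3 (0.96). The A2 and A1 lists were not tested against each other. All values are of whole pieces of cord, in which genes of other cells rose as well. Higher were 13 of 13 macrophage, 8 of 9 neutrophil and 8 of 12 endothelial genes. Which cells made the transcripts of the reactive astrocyte lists was not measured.

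Genes of astrocyte homeostasis had 9 of 13 members lower and 3 higher. Aldoc, a glycolytic enzyme, went from 1094 ± 134 to 549 ± 72.2 FPKM (log2 change −0.99). Glul, the enzyme that turns glutamate into glutamine, fell by 0.66 on the log2 scale. The 3 that rose were Aldh1l1 (1.05), Sox9 (0.82) and the water channel Aqp4 (0.65), and Kcnj10 (−0.16) did not pass. The homeostasis list itself did not pass camera (adjusted p = 0.081), though it did with no filter on low values (adjusted p = 0.023). The pan-reactive, A2 and A1 lists had camera adjusted p of 2.3e-07, 1.1e-07 and 2.8e-04. The same lists had adjusted p = 0.20, 0.20 and 0.25 with an estimated correlation.

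Inflammatory mediators rose in the injured cord, some from very low levels. Il1a and Tnf, which with C1q are known to induce an A1 state in astrocytes, were at 0.613 ± 0.426 and 0.227 ± 0.197 FPKM in sham and at 2.16 ± 0.880 and 1.56 ± 0.437 in SCI libraries. C1qa went from 64.8 ± 3.17 to 452 ± 29.1, a 6.97-fold rise. The log2 changes were 0.96 for Il1a (SE 0.27, limma adjusted p = 0.019), 1.06 for Tnf (SE 0.20, adjusted p = 0.0038) and 2.78 for C1qa (SE 0.08, adjusted p = 7.8e-06). The call on Il1a ended without sham replicate 1 (0.89), without sham replicate 3 (0.83) or without SCI replicate 2 (0.77). Cytokine genes had 8 of 9 members higher, led by Il1b (3.25) and Lif (3.17), with Tgfb1 at 2.63. Of the 9, 7 were highest in SCI replicate 2 among the injured libraries. Without that library 7 were higher, and Il1b and Lif were at 2.73 and 2.47. Il18 was lower (−0.37), a call that ended without sham replicate 2 (−0.35). Chemokine genes had 9 of 11 members higher, led by Ccl2 and Ccl7 (5.13). Cx3cl1, the neuronal ligand of the microglial receptor Cx3cr1, fell from 89.3 ± 4.32 to 38.1 ± 9.31 FPKM. Ccl5 (0.95) did not pass, except without sham replicate 3 or SCI replicate 3 (1.33 in both), and it was at 0.58 without SCI replicate 2. In camera the adjusted p was 0.0019 for cytokines and 1.5e-04 for chemokines. Neither held with an estimated correlation (adjusted p = 0.24 and 0.20).

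Complement genes had 9 of 11 members higher, and 10 when adjusted over the list alone. C3ar1 (4.22) and C5ar1 (3.86), the receptors of the C3a and C5a peptides, changed most, and C1qb reached 460 ± 50.1 FPKM from 64.8 ± 8.79. Cfb (1.03) and Serping1 (0.74) did not pass over all genes, although Cfb did without sham replicate 1 (1.35), and it was at 0.48 without sham replicate 3. Genes of lysosomes and phagocytosis had 12 of 13 members higher, with Cd68 at 4.27, the Fc receptor chain Fcer1g at 3.49 and Ctsb at 1.72. Lamp1 (0.17) did not pass, although it did without SCI replicate 2 (0.21) and under median-ratio scaling (0.27). Of the 13, 11 were highest in SCI replicate 2 among the injured libraries. Interferon response genes had 11 of 13 members higher, and 13 when adjusted over the list alone, among them Bst2 (2.21), Irf7 (1.58) and Ifit3 (0.70). The call on Ifit3 ended without sham replicate 1 (0.52), sham replicate 2 (0.66), SCI replicate 1 (0.59) or SCI replicate 3 (0.70), and Stat2 (0.32) did not pass over all genes, although it did without SCI replicate 2 (0.44). The camera adjusted p was 3.3e-07 for complement, 3.0e-09 for lysosomes and 8.7e-05 for interferon genes. In that order, the adjusted p was 0.23, 0.23 and 0.29 with an estimated correlation.

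Signalling and stress genes rose with them. The NF-kappaB and STAT3 list had 12 of 12 members higher, led by Socs3 and by Bcl3 (3.02), with Stat3 at 1.29. Immediate early genes, switched on within minutes of a stimulus, had 8 of 8 higher, led by Junb (2.96) and Fos (2.63). Inflammasome genes had 7 of 8 higher, with Pycard at 2.04 and Gsdmd, whose product forms pores in dying cells, at 1.85, while Il18 was lower. Genes of oxidative stress and NADPH oxidase had 9 of 12 higher, led by Hmox1, which degrades haem, at 10.4 ± 3.84 and 591 ± 114 FPKM, and by the oxidase subunit Cyba (3.36). Gpx4 was lower (−0.29), with Nqo1 (−0.04, and 0.048 under median-ratio scaling) and Gclm (−0.10) not past the threshold. The fall of Gpx4 did not pass without any 1 of the sham libraries, at −0.25, −0.29 and −0.33 without replicates 1, 2 and 3, nor without SCI replicate 1 (−0.33). The camera adjusted p of the signalling, immediate early, inflammasome and oxidative lists was 2.3e-07, 8.1e-06, 0.0012 and 2.0e-04. With an estimated correlation the adjusted p was 0.20, 0.23, 0.23 and 0.20.

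Neuronal genes were lower in the injured cord. Nefh, Nefm and Nefl, the neurofilament subunits of axons, fell 3.89-fold, 3.04-fold and 2.97-fold, and Nefl went from 1568 ± 178 to 527 ± 114 FPKM. Pan-neuronal genes had 10 of 11 members lower, and 11 when adjusted over the list alone. All 11 were lowest in SCI replicate 2, the library with the highest haemoglobin share. Tubb3 (−0.59) did not pass over all genes, though it did without SCI replicate 2 (−0.33) or SCI replicate 3 (−0.81). Genes of neurotransmitter identity and receptors had 12 of 12 members lower, and 11 were lowest in SCI replicate 2 among the injured libraries. The glycine transporter Slc6a5 went from 127 ± 8.65 to 50.1 ± 11.8 and Slc32a1, the vesicular transporter of GABA and glycine, from 105 ± 8.58 to 40.3 ± 9.67. Slc18a3, the vesicular transporter of acetylcholine, whose gene lies inside that of Chat, went from 40.2 ± 4.68 to 7.89 ± 3.65. Genes linked to axon regeneration had 8 of 10 members higher: Sprr1a, Atf3 (4.59), Jun (1.60) and Gap43 (0.58) were among them, and Npy (−0.32) and Vip (−0.12) did not pass. Without SCI replicate 3, which held genes of sensory ganglion neurons, 7 of the 10 were higher. Jun was also counted in the immediate early list, and which cells made the transcripts of the regeneration list was not measured. The camera adjusted p was 2.1e-04 for the pan-neuronal, 2.9e-05 for the neurotransmitter and 5.8e-04 for the regeneration list. These became adjusted p = 0.38, 0.31 and 0.23 with an estimated correlation.

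Hox genes, which mark position along the cord, were no fixed list and were examined after the fall of Hoxd10 was seen. Hoxd10 was at 63.3, 31.6 and 43.0 FPKM in sham and at 0.70, 0.87 and 12.9 in SCI replicates 1, 2 and 3, and Hoxc10 went from 86.0 ± 2.12 to 31.0 ± 11.6. The 6 tested Hox genes of paralog groups 10 and 11, which are expressed in the caudal cord, had a median log2 change of −1.71, with 5 past the threshold. The 19 genes of groups 4 to 9 had a median of −0.55, with 10 past the threshold, and the 5 genes of groups 2 and 3 had a median of −0.52, with 2 past the threshold. Across the 30 Hox genes tested, the change correlated with paralog number (Spearman rho = −0.62, permutation p = 3.4e-04; Pearson r = −0.62, permutation p = 5.0e-05), where genes are not independent replicates. The medians of groups 2 to 3 and 4 to 9 were close, so this was not a steady fall along the groups.

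**Figure D2:**
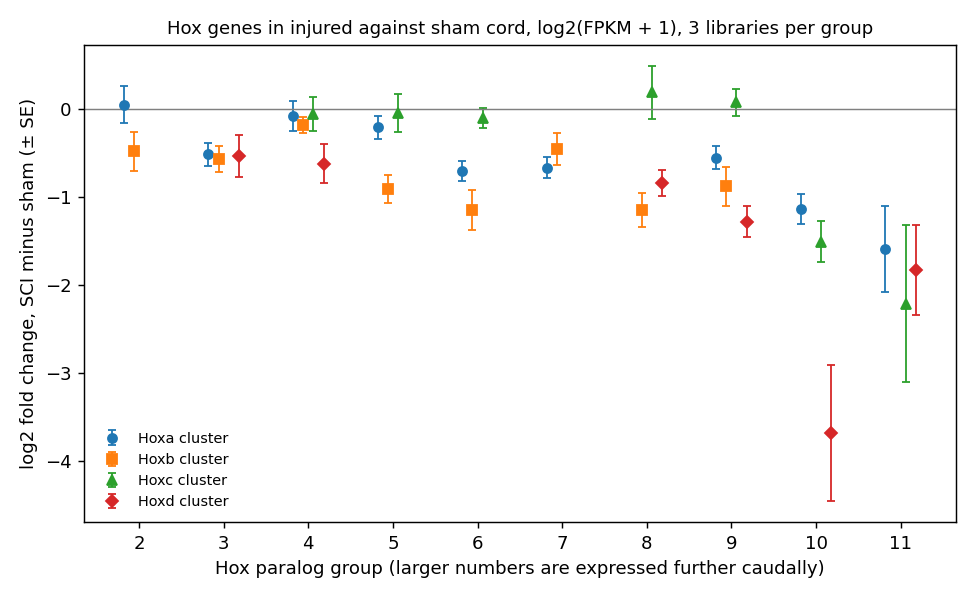
Log2 change of 30 Hox genes (SCI minus sham on log2(FPKM + 1), ± SE) against paralog group, with 1 marker per gene and a marker shape for each cluster. Hoxd10 sits lowest at −3.68, and the genes of groups 10 and 11 lie at −1.14 or below.

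Myelin genes were mostly lower, and genes of oligodendrocyte precursors went both ways. Opalin went from 53.5 ± 5.71 to 25.2 ± 5.58 FPKM. Mbp, myelin basic protein, went from 3202 ± 87.9 to 2165 ± 93.9. Genes of mature oligodendrocytes and myelin had 9 of 13 members lower, and all 13 were lowest in SCI replicate 2 among the injured libraries. Mag (−0.39), Ermn (−0.49) and Myrf (−0.03, and 0.061 under median-ratio scaling) did not pass, and Cldn11 was higher (0.66). Ermn did pass without SCI replicate 2 (−0.21), and without that library Mag was at −0.11 and Myrf at 0.26. The call on Cldn11 ended without any 1 library other than SCI replicate 2, with log2 changes from 0.50 to 0.69. The call on Mbp ended when no filter on low values was set (adjusted p = 0.078). The list had a camera adjusted p of 0.014, and an adjusted p of 0.51 with an estimated correlation. Among 11 precursor genes, Pdgfra, a receptor of these precursors, rose from 10.5 ± 1.14 to 28.0 ± 2.23 and Cspg4 from 3.94 ± 0.447 to 7.47 ± 1.24. Lhfpl3 was lower (−0.48), and 8 did not pass, among them Bcas1 (0.18) and Olig1 (0.14), which passed without SCI replicate 2 (0.28 and 0.27), and Neu4 (−0.35), which passed without SCI replicate 3 (−0.52). The precursor list did not pass camera (adjusted p = 0.82), and its median of −0.12 and mean of 0.05 differ in sign. Which cells made the Pdgfra and Cspg4 transcripts was not measured, and 13 of 14 fibroblast and scar genes were higher as well.

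Genes of vessels and scar were higher. Endothelial and barrier genes had 8 of 12 members higher, and 9 when adjusted over the list alone. Cdh5, the cadherin of endothelial junctions, went from 9.55 ± 1.14 to 56.0 ± 16.8 FPKM, Pecam1 from 11.9 ± 1.35 to 48.1 ± 5.29 and Cldn5 from 48.1 ± 5.39 to 103 ± 17.4. Slco1a4, a transporter of the blood-brain barrier, was lower (−0.70). Ly6c1 (0.40), Abcb1a (0.07) and Ocln (0.09, and −0.0091 under quantile normalization) did not pass, though Ly6c1 did without SCI replicate 2 (0.58). Genes of fibroblasts and fibrous scar had 13 of 14 members higher, with Tnc at 4.95 and Fn1, fibronectin, at 4.21. Of the 14, 12 were highest in SCI replicate 2 among the injured libraries. Sparc (0.35) did not pass, although it did without sham replicate 1 (0.53) and under median-ratio scaling (0.44). The camera adjusted p was 0.0022 for the endothelial and 6.0e-06 for the fibroblast list. Neither held with an estimated correlation (adjusted p = 0.20 and 0.27).

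Among pericyte and smooth muscle genes 4 of 8 were higher, and 6 when adjusted over the list alone. These 4 were Tagln (3.14), Pdgfrb (1.12), Acta2 (0.93) and Cnn1 (0.45). The call on Cnn1 ended without any 1 library, at log2 changes of 0.39 to 0.51. Myh11 was lower (−0.62), and Rgs5 (−0.04, and 0.049 under median-ratio scaling), Kcnj8 (0.36) and Abcc9 (0.25) did not pass over all genes. Kcnj8 did without sham replicate 1 (0.45). Among 10 genes of chondroitin sulphate proteoglycans 6 were higher, among them Vcan (1.70) and the sulphotransferase Chst11 (1.31). Bcan, brevican of perineuronal nets, fell 3.16-fold, from 148 ± 1.60 to 46.9 ± 7.80 FPKM, and Acan was lower (−0.65). Cspg5 (−0.25) and Chpf (−0.25) did not pass. Ependymal genes had 4 of 6 members lower, and 5 when adjusted over the list alone: Ccdc153 (−1.06), Tmem212 (−0.86), Fam183b (−0.61) and Foxj1 (−0.53), a regulator of motile cilia. Dynlrb2 (−0.73) and Rarres2 (0.37) did not pass over all genes, although Dynlrb2 did without sham replicate 2 (−0.92) or SCI replicate 3 (−0.99), and it was at −0.48 without sham replicate 1. Rarres2 ranged from 0.070 without sham replicate 2 to 0.67 without sham replicate 1. The call on Tmem212 ended without SCI replicate 1 (−0.77) or SCI replicate 3 (−0.88), and its size was −0.53 without sham replicate 1. None of these 3 lists passed camera (adjusted p = 0.066, 0.17 and 0.081). The ependymal list did pass without sham replicate 2 (adjusted p = 0.049) and with no filter on low values (0.011), and the pericyte list with a filter at 5 FPKM (0.037) and with no filter (0.019).

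Genes of cell division rose. Of 16 cell cycle members 16 were higher, with Top2a going from 0.443 ± 0.0416 to 31.9 ± 6.21 FPKM, Mki67 changing by 4.37 on the log2 scale and Pcna going from 44.1 ± 2.44 to 140 ± 7.98. Genes of mitochondrial respiration had 10 of 10 members lower, among them Sdha (−0.69), Cox5a (−0.57) and Cox4i1 (−0.53). Genes of cholesterol synthesis had 12 of 16 lower, among them Hmgcs1 (−0.58), while Mvk (−0.16), Fdps (−0.16), Sqle (−0.23) and Lss (−0.23) did not pass. Mvk did without SCI replicate 1 (−0.30). Without SCI replicate 2, Mvk, Fdps, Sqle and Lss were at −0.061, 0.017, −0.075 and −0.068. Genes of lipid efflux and storage had 8 of 10 higher, with the lipid droplet coat Plin2 at 3.14 and the cholesterol exporter Abca1 at 2.37. Apoe did not pass, and Abcg1 was lower (−0.33), a call that ended without sham replicate 1 (−0.32) or sham replicate 3 (−0.31). In SCI replicate 2, the library with the highest haemoglobin share, 10 of 10 respiration and 16 of 16 cholesterol genes were lowest and 15 of 16 cell cycle genes highest among the injured libraries. The camera adjusted p of these 4 lists was 5.5e-12, 0.0013, 0.0014 and 0.0011. With an estimated correlation the adjusted p was 0.23, 0.39, 0.45 and 0.23.

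Among 12 hypoxia and glycolysis genes 6 were higher, with Hk2 at 2.60 and Ldha at 2.01, and Bnip3 was lower (−0.89). Aldoa (−0.31), Pkm (−0.15), Vegfa (0.45), Pgk1 (0.17) and Pdk1 (0.12) did not pass. Pgk1 did pass without SCI replicate 2 (0.19). Without SCI replicate 3, Aldoa (−0.38) and Vegfa (0.81) did pass, and the list, at a camera adjusted p of 0.071 with all libraries, had 0.038. With no filter on low values the list had 0.025. Vegfa was at 0.044 without SCI replicate 2.

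Markers of other tissues and of blood differed between single libraries. Schwann cell genes, which mark nerve roots, had 5 of 8 members lower, among them Prx (−2.40), Ncmap (−1.62), Pmp22 (−1.27) and Drp2 (−1.27). Cdh19 was higher (0.67), and Egr2 (−0.15) and Pmp2 (−1.05) did not pass, although Pmp2 did without SCI replicate 2 (−1.63) and Egr2 without sham replicate 2 (−0.72). The call on Ncmap ended without sham replicate 1 (−1.44) or sham replicate 3 (−1.32). The list did not pass camera (adjusted p = 0.10), although it did without sham replicate 2 (adjusted p = 0.0038) and with no filter on low values (adjusted p = 0.041). Skeletal muscle genes had 0 of 7 members past the threshold by limma, and 0 at an unadjusted p under 0.05. Acta1 was at 15.7 ± 14.8 in sham and 81.2 ± 124 in SCI libraries, and Mylpf at 12.0 ± 9.65 and 30.7 ± 42.5.

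Red blood cell genes had 3 of 5 members higher, and 5 when adjusted over the list alone. Hba-a1, Hba-a2 and Hbb-bs had log2 changes of 3.05, 3.00 and 2.98, while Hbb-bt (2.92) and Alas2 (2.75) did not pass over all genes, although both did without SCI replicate 3 (4.02 and 3.91). Hbb-bt also passed without SCI replicate 2 and with a filter at 5 FPKM (adjusted p = 0.048), and Alas2 was at 1.26 without SCI replicate 2. Haemoglobin genes took 6.16% of the FPKM of SCI replicate 2, and without that library the changes of Hba-a1, Hba-a2, Hbb-bs and Hbb-bt were 1.74, 1.68, 1.62 and 1.51. The calls on Hba-a1, Hba-a2 and Hbb-bs ended without any 1 sham library or without SCI replicate 1, at log2 changes of 2.92 to 3.29. The list did not pass camera (adjusted p = 0.082), though it did without SCI replicate 3 (adjusted p = 0.012) and with no filter on low values (adjusted p = 0.028). Neutrophil genes had 8 of 9 members higher, led by S100a8 (3.90) and S100a9 (3.33). Mmp9 (0.72) was not past the threshold except without SCI replicate 3 (1.13), and was at 0.30 without SCI replicate 2. All 9 neutrophil genes were highest in SCI replicate 2 among the injured libraries. Their median log2 change of 2.45 was 1.85 without that library and 3.02 without SCI replicate 3. Their camera adjusted p was 0.0022, and with an estimated correlation the adjusted p was 0.40. The call on the neutrophil list ended with a filter at 5 FPKM (adjusted p = 0.065). Among lymphocyte genes only Cd79b and Lck could be tested, and Cd79b was higher (0.93, adjusted p = 0.033 by limma). Lck was at 0.22. The call on Cd79b ended without sham replicate 1 (0.83), sham replicate 3 (0.83), SCI replicate 1 (1.00) or SCI replicate 2 (0.63). Among 4 adipocyte genes Fabp4 was higher (0.89), and none passed when adjusted over the list alone. Cfd (−0.09), Adipoq (0.54) and Cidec (0.27) did not pass. Adipoq and Cidec were at 0.22 and 0.15 without sham replicate 1, and at 0.74 and 0.41 without sham replicate 3. The call on Fabp4 ended without sham replicate 1 (0.65), sham replicate 2 (0.91), SCI replicate 1 (1.04) or SCI replicate 3 (0.59). The skeletal muscle and adipocyte lists had camera adjusted p of 0.67 and 0.37.

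In total, 21 of the 37 tested lists were higher and 5 lower in camera at the preset correlation, and 11 did not pass. The 5 lower lists were myelin, pan-neuronal, neurotransmitter, cholesterol synthesis and mitochondrial respiration. With an estimated correlation camera passed 0 lists, with adjusted p of 0.20 to 0.51 among those 26 and 7 lists at an unadjusted p under 0.05, while fry called 25 higher and 7 lower. Other divisions of the 6 libraries into 3 and 3, which mix the groups, gave up to 27 lists in camera at the preset correlation.

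**Figure D3:**
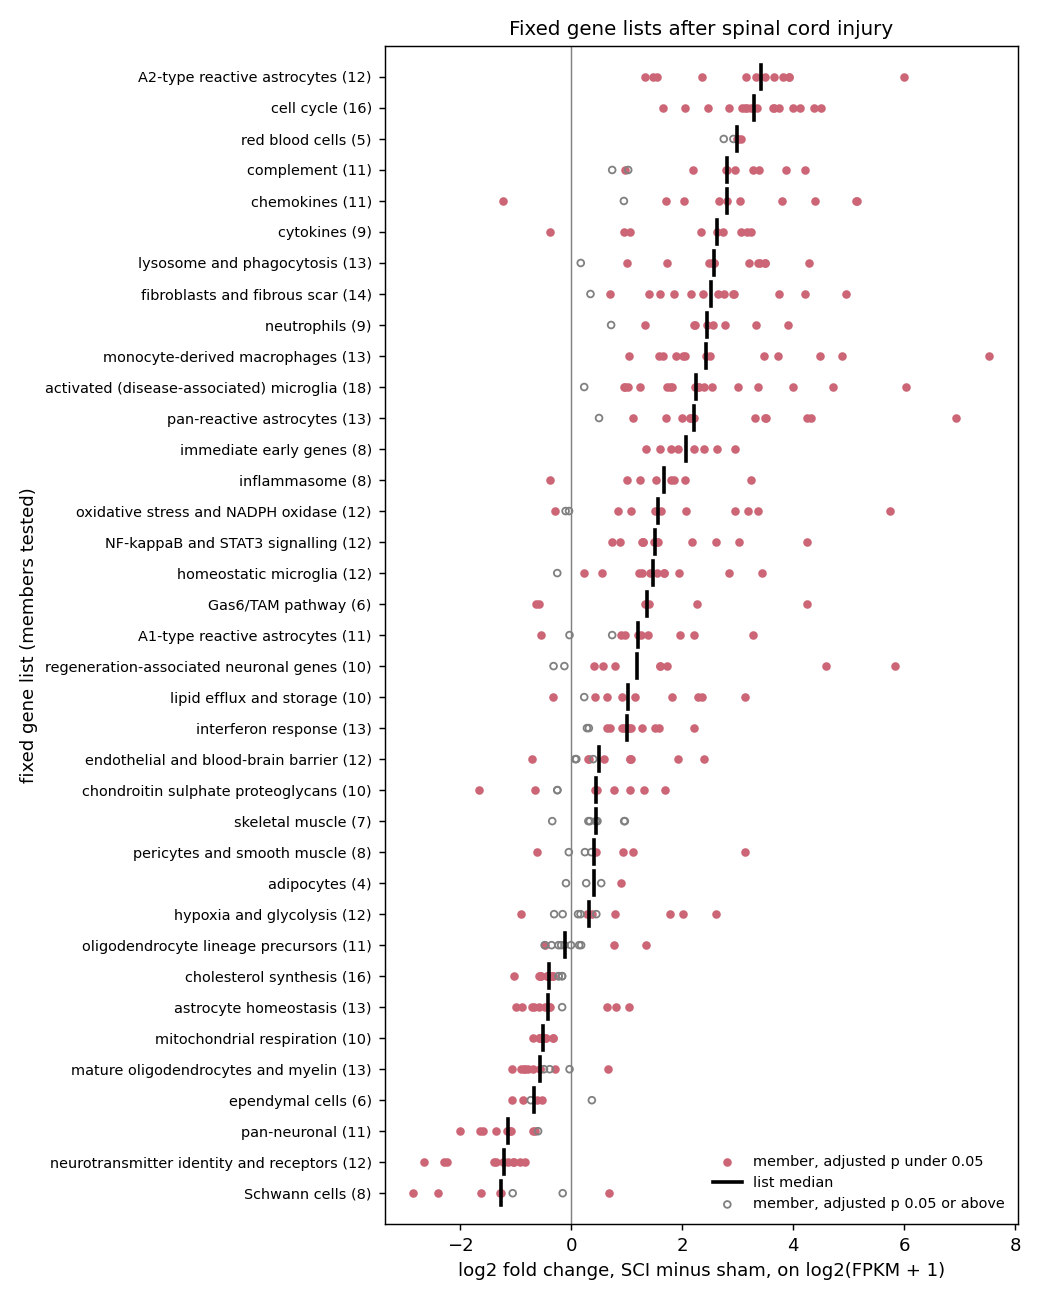
Log2 change (SCI minus sham on log2(FPKM + 1)) of each tested member of the 37 fixed lists, with filled points for members past the threshold, open points for the rest and a black bar at each list's median. A2-type reactive and cell cycle genes have the highest medians, 3.41 and 3.29, and Schwann cell and neurotransmitter genes the lowest, −1.27 and −1.21.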

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

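The median-ratio scaling and the fit without mitochondrial and haemoglobin genes were chosen after the results were seen. No gene past the threshold had the opposite sign under any of the 14 alternative gene fits. With no filter, the filter at 5 FPKM, treat and the replicate block, a gene's log2 change equals that of the main fit by construction. No sign could change in those fits. The count of genes higher ranged from 3686 (filter at 5 FPKM) to 5383 (median-ratio scaling), and of genes lower from 4136 (without sham replicate 1) to 6364 (quantile normalization), apart from treat against a log2 change of 1. Treat asks for a larger change by its construction and left 846 higher and 44 lower. Under treat Gas6 (−0.57), Axl (1.40), Mertk (1.33) and Tyro3 (−0.64) no longer passed (adjusted p = 1, 0.065, 0.33 and 1), and Pros1 did (adjusted p = 8.6e-04). Gas6, Axl, Mertk and Pros1 passed in every other fit, and Tyro3 in every other fit but those without sham replicate 2 or 3, ranging from −0.80 to −0.43 when 1 library was left out. With no filter 25 lists were higher in place of 21, and 8 lower in place of 5. The genes that camera sets a list against then came from 33526 tested, in place of 17435. Their median log2 change was −0.0095, in place of −0.076. A list that passed with no filter was therefore set against another background, and how far this made the difference was not tested. With an estimated correlation 0 lists were higher and 0 lower. The estimates were 0.86 for pan-neuronal and 0.67 for cell cycle genes, against the preset 0.01. Lists with estimates below 0.01 also lost their calls, as chemokines (−0.012) and endothelial genes (−0.0028) did. A larger correlation is therefore not the whole cause. With an estimated correlation camera also takes its degrees of freedom from the few libraries in place of the genes, which by itself gives larger p-values. The shares of the 2 in the loss of calls were not separated. A list without a call here is not shown to be unchanged. The share of calls that were higher was 46.4%, against 40.8% under quantile normalization and 52.6% under median-ratio scaling.

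Genes without a call that passed were Ly6c1, Aldoa, Serping1, Tubb3 and Dynlrb2 under quantile normalization, and Ly6c1, Serping1, Kcnj8, Abcc9, Stat2 and Pgk1 among others under median-ratio scaling. Genes that changed sign had not passed. These were Apoe (−0.025) and Ocln (−0.0091) under quantile normalization, and Rgs5 (0.049), Fbln5 (0.050), Myrf (0.061) and Nqo1 (0.048) under median-ratio scaling; the cause was not tested. When 1 library was left out, Rgs5 ranged from −0.16 to 0.040, Acta1 from −0.63 to 2.29, Mylpf from −0.78 to 1.48, Cfd from −0.31 to 0.17, Fbln5 from −0.15 to 0.041 and Myrf from −0.24 to 0.26. Npy ranged from −0.55 to 0.018, Ocln from −0.030 to 0.16, Egr2 from −0.72 to 0.14, Nqo1 from −0.14 to 0.039 and Fdps from −0.28 to 0.017.

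With the replicate number as a block, 4398 genes were higher and 5045 lower. Under the block Tmem212, Gpx4 and Cnn1 did not pass (adjusted p = 0.050, 0.063 and 0.077), while Npy, Ly6c1, Kcnj8, Hbb-bt, Alas2 and the red blood cell list did. Same-numbered samples deviated with r of −0.008, −0.039 and 0.022, and 1 of the 3 numbers had its samples correlate best with each other, so the numbers were not taken to pair samples. DESeq2's Wald test, DESeq2 size factors in an edgeR fit, upper quartile factors and library totals without TMM factors were not run, since they need counts. The unknown depth gives no counting error for low genes.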

Other observations

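The tests of Hox genes, cholinergic genes, blood and ganglion genes and dilution were chosen after the results were seen.

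Trf, which encodes the iron carrier transferrin, rose from 974, 1019 and 993 FPKM in the sham libraries to 3174, 1471 and 2579 in SCI replicates 1, 2 and 3 (log2 change 1.20, limma adjusted p = 0.0062), while 9 of 13 myelin genes were lower. Apoc2, an apolipoprotein, was listed at 0 in every sham library and at 24.8, 39.6 and 21.4 in the SCI libraries. SCI replicate 3 held genes of sensory ganglion neurons: Avil at 17.3, Scn10a at 6.60, Scn11a at 5.14, Trpv1 at 2.86 and Mrgprd at 1.96 FPKM, each at 0.50 or lower in the other libraries. All 7 such genes examined were highest in that library among the injured ones, and 2 of the 7 had a sham mean of at least 1 FPKM. The muscle gene Acta1 was at 224 FPKM in SCI replicate 3, against 16.4 and 2.94 in SCI replicates 1 and 2.

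Cholinergic genes lay below the median of the pan-neuronal list: Chat, Slc5a7 and Slc18a3 had log2 changes of −2.23, −2.65 and −2.28. A loss of all neurons alike stays open, because these genes were chosen after the fall of Slc5a7 was seen, so that their distance from the pan-neuronal median (difference −1.14, SD of pan-neuronal members 0.44) decides nothing. Injured pieces with less caudal cord stay open as part of the cause. Hox genes of groups 10 and 11 lay below those of groups 4 to 9 (difference of medians −1.15, and −1.60 to −0.82 when 1 library was left out). They were however examined because Hoxd10, a member of group 10, was among the largest falls. The other genes of groups 10 and 11 lay at −1.14 or below, and those of groups 4 to 9 between −1.28 and 0.19. Sham libraries differed too, with Hoxc11 at 20.6, 2.5 and 9.5 FPKM in replicates 1, 2 and 3. Motor neuron loss at the lesion stays open too. The cholinergic median lay below that of the caudal Hox genes by less than their spread (difference −0.58, SD 0.90, and −0.08 without sham replicate 2). That spread includes Hoxd10, and the cells that made the Hox transcripts were not measured, so the comparison cannot decide it. Chodl, a marker of fast motor neurons, was named because its fall was among the largest, and so it decides nothing either. Hox values in adult cord could also change with cell loss, which was not tested.

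Haemoglobin FPKM in SCI replicate 2 was 14.4 times the mean of the other injured libraries. Displacement of other transcripts by haemoglobin would shift all others by −0.09 on the log2 scale, and pan-neuronal genes of that library differed by −0.67, which argues against it as the whole cause. Blood left in that piece stays open: 100% of 13 neutrophil and platelet genes were highest there among injured libraries, though 9 of the 13 had a sham mean of at least 1 FPKM. Platelet genes stood less far apart than haemoglobin, with Pf4 at 349.6 FPKM against 234 and 110.1, Ppbp at 45.7 against 40.1 and 4.63, and haemoglobin at 44788 against 4695 and 1522. The other platelet genes were low, with Itga2b at 3.5 against 2.63 and 2.09 and Gp9 at 2.45 against 0.58 and 1.09. Gp9 was at 1.65 in sham replicate 1. A larger lesion or more bleeding stays open too: 100% of 24 pan-neuronal and myelin genes were lowest there. Such counts are not particular to these genes. In the same library 16 of 16 cholesterol and 7 of 7 skeletal muscle genes were lowest, and 15 of 16 cell cycle genes highest. Genes of a list move together (estimated correlation 0.86 pan-neuronal, 0.82 myelin, 0.89 neutrophil), so the 24 and the 13 are not independent. The share over all tested genes was not computed.

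Gas6 and Tyro3 fell while Axl, Mertk and Pros1 rose. Uniform dilution of resident cells by incoming ones would lower resident cell types alike. Pan-neuronal genes lay below astrocyte homeostasis genes (difference of medians −0.73, permutation p = 2.6e-04 across genes, SD within lists 0.53), while Aldh1l1, Sox9 and Aqp4 rose. These values argue against uniform dilution as the whole cause of the changes in these lists, with limits. They do not test the fall of Gas6 (−0.57) and Tyro3 (−0.64), which lay near the myelin median, so dilution stays open for these genes. Regulation within astrocytes could also part the medians and was not tested. Genes of a list are not independent replicates (estimated correlation 0.86 for pan-neuronal genes), so the permutation p does not measure the spread between samples. Without SCI replicate 2 the difference of medians was −0.49, less than the SD with all libraries. The myelin median of −0.56 lay closer to the astrocyte median of −0.41 than that SD, as dilution alike would need. Fewer neurons may account for part of the fall and stays open, with the pan-neuronal median below the mean of Gas6 and Tyro3 (difference −0.54), since the cells that make Gas6 were not measured.

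With 3 samples against 3 there are 10 splits, and the share of splits cannot be under 0.1. As many genes as in the real split (10024) were past the threshold in 1 of the 10, the real one. The highest of the others was 0 by limma, with 113 to 181 genes at an unadjusted p under 0.05. Each of the other splits has sham and SCI libraries on both sides. The difference between groups then counts as spread within a side, which keeps the gene count low. The 0 is therefore no measure of how many genes would pass without an effect of injury. As many lists as in the real split (26) were past the threshold in 3 of the 10, and the highest of the others was 27.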
